A study of Mus musculus with 8 samples.

How the data were processed

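RNA-seq libraries were made from C3H10T1/2 cells expressing epitope-tagged histone transgenes, grown in serum-containing medium, with RNA extracted by Trizol and libraries made with an Illumina TruSeq kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.32, STAR 2.3.0e, featureCounts 1.4.4 and DESeq2 (no version), and the mouse build mm10. The order of these steps, their settings, the gene annotation and whether counting used strand are not given in the sources used here. The deposited values are on a log2 scale: a variance-stabilising transformation by the authors of reads per gene divided by 1 size factor per library, with no correction for gene length. The deposited table holds 31276 genes in 8 columns, 1 per library, each matched to a library by its transgene name.

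The lowest value, 5.95, is shared by all libraries and stands for 0 reads. Inverting the parametric form of the transformation turned 100% of values into whole reads, within 0.001 reads (largest deviation 1.51e-07), and gave the depth of each library: about 62788500 reads in H3.3 WT, 64093400 in K36A, 68021000 in K36I, 61840300 in K36L, 61139900 in K36M and 63433600 in K36R, with 45448200 in H3.1 K36M and 53199100 in H3.1 K36R. Normalised reads in the text are these reads divided by the library's size factor. At these depths 3 reads, the limit that a count of 0 allows, make up 4.41e-06% to 6.60e-06% of a library, and this covers counting error only. On the log2 scale of the transformation, differences of genes with few reads are smaller than the difference of their logged reads.

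Genes entered the tests where their mean over the 8 libraries was at least 1 above the lowest value, about 31.1 normalised reads. This kept 14215 genes and left out 17061, of which 8275 had 0 reads in every library. The class comparison set H3.3 K36M, H3.3 K36I and H3.1 K36M against H3.3 WT, K36A, K36L and K36R and H3.1 K36R, using limma 3.58.1 in R 4.3.3 with an intensity trend, two-sided, with Benjamini-Hochberg adjustment at 0.05. K36M against K36R used the 2 libraries of each over both histones, and H3.1 against H3.3 used the same 4 libraries with substitution as a term. Mutants against H3.3 WT had 1 library a side, so genes differing by at least 1 were counted without a test. Nothing in the labels says that lines were derived or cultured more than once, so the p-values measure the spread between these lines alone, part of which may be technical.

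In all, 32 gene lists holding 888 genes were written before the data were examined, and 885 of the genes were found in the table. The 28 lists with at least 5 genes past the filter were tested in the class comparison with limma's camera (preset correlation 0.01), and repeated with an estimated correlation, under which 0 lists passed (3 at unadjusted p under 0.05). The self-contained test fry called 7 lists for a shift in one direction, not all the same as those of camera, and 25 for change in either. Against H3.3 WT, list medians were placed among 10000 random lists of the same size matched on mean expression. The H3.1 K36M signature took the 200 highest and 200 lowest genes of H3.1 K36M minus H3.1 K36R, with 1000 bootstrap resamples over genes. The grouping into classes, the tests, the filter and the rule for named genes were also fixed before the data were examined.

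The rule named, for the class comparison, the 15 genes that rose and the 15 that fell most among called genes whose classes do not overlap. It named 6 each way for K36M against K36R and for H3.1 against H3.3 where as many passed, 5 each way for each mutant against WT, and up to 4 called members of each list, or the 2 largest differences said not to pass. It also named H3f3a, H3f3b, Ezh2, Eed, Suz12, Setd2, Nsd1, Whsc1, Whsc1l1 and Ash1l in any case, and left out predicted genes, clones and small RNA genes. Members named beyond the rule (Sox9, Matn3, Fmod, Smo, Gli1, Ptch1, Lamb1, Col4a1, Col1a1, Hoxa10, Ptprc, Epcam, Cxcl1, Serpina3h, Casp4 and Trim30a) were chosen after their values were seen.

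Coordinates come from GENCODE M21 on GRCm38, the assembly behind mm10, by gene symbol, for 12954 of the 14215 genes (91.1%). Of the 158 genes the rule named, 53 have exons overlapping those of another annotated gene, 47 of them on the opposite strand, and with strand not given their reads cannot be separated. In the class comparison these are Sprr2a1, Sprr2a2, Lcp1, Heph, Slfn5, Eln, Gas7, Sorbs2 and Prelp.

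The steps were tested on simulated data. With 100 genes changed by each size among 14215, the class test recovered 73% of changes of 1 and 94% of changes of 2 in log2 reads. It called 7 of 14015 unchanged genes. The K36M against K36R test recovered 1% and 47%, and the H3.1 against H3.3 test 0% of either size. Changes were planted only in genes with more reads than the filter requires, and noise was drawn independently for each gene and library. The shares therefore do not cover genes near the filter or variation that lines share. Sizes were planted in log2 reads, with noise sized by the spread on the deposited scale. On that scale differences of genes with few reads are smaller, so the shares do not apply directly to the reported differences. Alternatives covered the filter, the scaling, the log2 offset on recovered reads, the limma settings, each library left out, the grouping, the list tests and the signature size. Alternatives added after the data were seen were limma voom on the recovered reads, chromosome medians subtracted, the fit without the libraries with the most 45S ribosomal reads, and the exact permutation of lists. Figures were drawn with matplotlib 3.10.9.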

Results

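Gene expression was measured by RNA-seq in C3H10T1/2 cells, a mouse mesenchymal line of embryonic origin that can take up cartilage, bone, fat and muscle fates, stably expressing tagged histone H3 transgenes. The labels describe 8 libraries, 1 per transgene. Of these, 6 carried histone H3.3 (wild type, written WT, or K36A, K36I, K36L, K36M and K36R) and 2 carried histone H3.1 (K36M and K36R). In K36M the lysine at position 36, a site of histone methylation, is replaced by methionine, and the other names give the other replacing residues in the same way. The design asks how these substitutions alter the transcriptome of the cells.

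No transgene had a replicate library, so libraries were compared as classes. The 3 libraries with K36M or K36I, substitutions described in the literature as inhibiting H3K36 methyltransferases, were set against the other 5. Lines of a class carry different transgenes, so n counts lines, and each test asks whether a class difference exceeds the spread between lines. Recovered depth was about 45448200 reads in H3.1 K36M and 53199100 in H3.1 K36R, and it lay between 61139900 and 68021000 in the H3.3 libraries. Of the 31276 genes listed, 14215 passed the filter on low values. Differences are given on the deposited log2 scale, with normalised reads beside them.

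The libraries parted by class. On the leading principal component, which held 52.4% of the variance, the K36M and K36I libraries lay between -45.0 and -35.8 and the other 5 between 18.1 and 32.5. The next component, with 25.1% of the variance, set the H3.1 libraries (-33.8 and -36.1) apart from the H3.3 libraries. H3.3 K36M and H3.3 K36I differed from each other by at least 1 in 165 genes, and H3.1 K36M differed from them in 713 and 869. The 15 pairs across the classes differed in 864 to 1465 genes, so the counts within and across classes overlap. The 10 pairs within the other class differed in 146 to 704 genes.

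**Figure D1:**
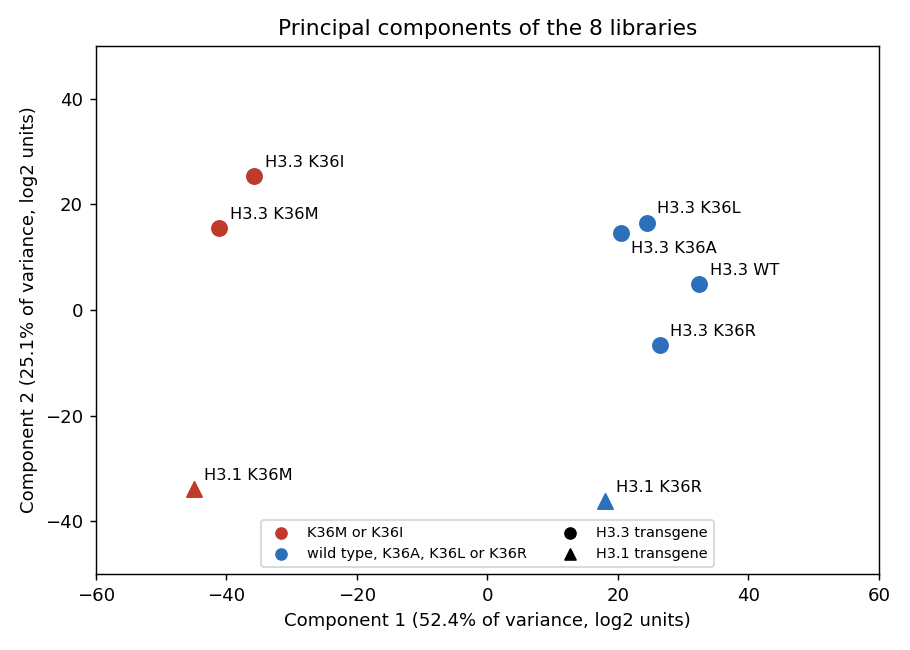
Scores of the 8 libraries on the leading principal components of 14215 genes, in log2 units, with colour for class and shape for histone. The 3 red K36M or K36I libraries lie at -45.0 to -35.8 on the horizontal axis and the 5 blue libraries at 18.1 to 32.5, while the H3.1 libraries lie lowest on the vertical axis.

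Cd53 and Lcp1, known from leukocytes, were among the genes that rose most in the K36M and K36I lines, and the matrix gene Eln and the cartilage regulator Sox6 among those that fell most. Cd53, a tetraspanin of leukocytes, rose by 4.70 on the log2 scale (SE 0.39, adjusted p = 2.98e-04), from 115 ± 84.1 normalised reads (SD, n = 5) to 5712 ± 3105 (SD, n = 3). Lcp1, a leukocyte actin-bundling protein, rose by 3.65 (SE 0.55, adjusted p = 0.00400). Eln, which encodes elastin, fell by 5.44 (SE 0.70, adjusted p = 0.00200), from 6039 ± 5655 to 15.9 ± 13.0 normalised reads. Sox6, a transcription factor of cartilage formation, fell by 3.81 (SE 0.54, adjusted p = 0.00298), from 1781 ± 1039 to 24.3 ± 10.8 normalised reads. Between all 3 libraries and the other 5, 1887 of 14215 genes passed the test (limma, adjusted p under 0.05), of which 917 were higher and 970 lower in the K36M and K36I lines.

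The largest differences among genes that rose belonged to Sprr2a2 (6.08, SE 0.75) and Sprr2a1 (5.42, SE 0.72), small proline-rich proteins of the cornified envelope. These copies overlap on chromosome 3 (92215920 to 92256724 and 92215799 to 92221911, GRCm38), so the share of reads that belongs to each is uncertain. The kinase-like gene Styk1 had the smallest SE of these 15 genes, at 3169 ± 304 normalised reads (n = 3) against 127 ± 30.0 (n = 5), a rise of 3.82 (SE 0.13, adjusted p = 4.72e-06). The Schlafen family members Slfn4 and Slfn5, which lie near each other on chromosome 11, rose by 4.36 (SE 0.28) and 3.36 (SE 0.22). Il33, an alarmin cytokine, rose by 3.50 (SE 0.66), the transmembrane glycoprotein gene Gpnmb by 3.44 (SE 0.59) and the ferroxidase gene Heph by 3.56 (SE 0.60). Ankrd1 (3.39, SE 0.44), Ppef1 (3.41, SE 0.69), Arhgap36 (3.28, SE 0.54), Hoxb9 (3.26, SE 0.53) and Prl2c3 (3.27, SE 0.87) completed the group. Prl2c3 has near-identical copies in the proliferin family and had the weakest call of the 15 (adjusted p = 0.0400).

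Among genes that fell, several encode matrix or secreted proteins. Prelp, a leucine-rich repeat proteoglycan, fell by 3.69 (SE 0.25, adjusted p = 1.21e-04), as did the collagen gene Col28a1 (-3.63, SE 0.57). Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, fell by 3.76 (SE 0.36), from 14910 ± 3474 to 1137 ± 865 normalised reads. Pappa, a protease of IGF-binding proteins (-3.86, SE 0.53), C1qtnf3 (-4.25, SE 0.62) and the cartilage-associated secreted protein gene Cytl1 (-4.02, SE 0.75) fell too. Falls were also seen in Sorbs2 (-4.33, SE 0.49), Nebl (-3.94, SE 0.42), Pgm5 (-4.01, SE 0.77) and Gas7 (-4.59, SE 0.41), which are linked to the cytoskeleton or cell contacts. Wscd2 fell by 4.97 (SE 0.25, adjusted p = 2.46e-05), and the lipase inhibitor gene G0s2 (-3.94, SE 0.23) and Epas1, which encodes HIF-2alpha (-3.89, SE 0.52), fell with it. By the rule for naming, all 30 had no overlap between the 3 libraries and the other 5, as had 21.5% of all genes tested, against 3.57% by chance. When each library was left out in turn, 27 of the 30 kept their call in every fit, the exceptions being Prl2c3, Ppef1 and Pgm5.

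**Figure D2:**
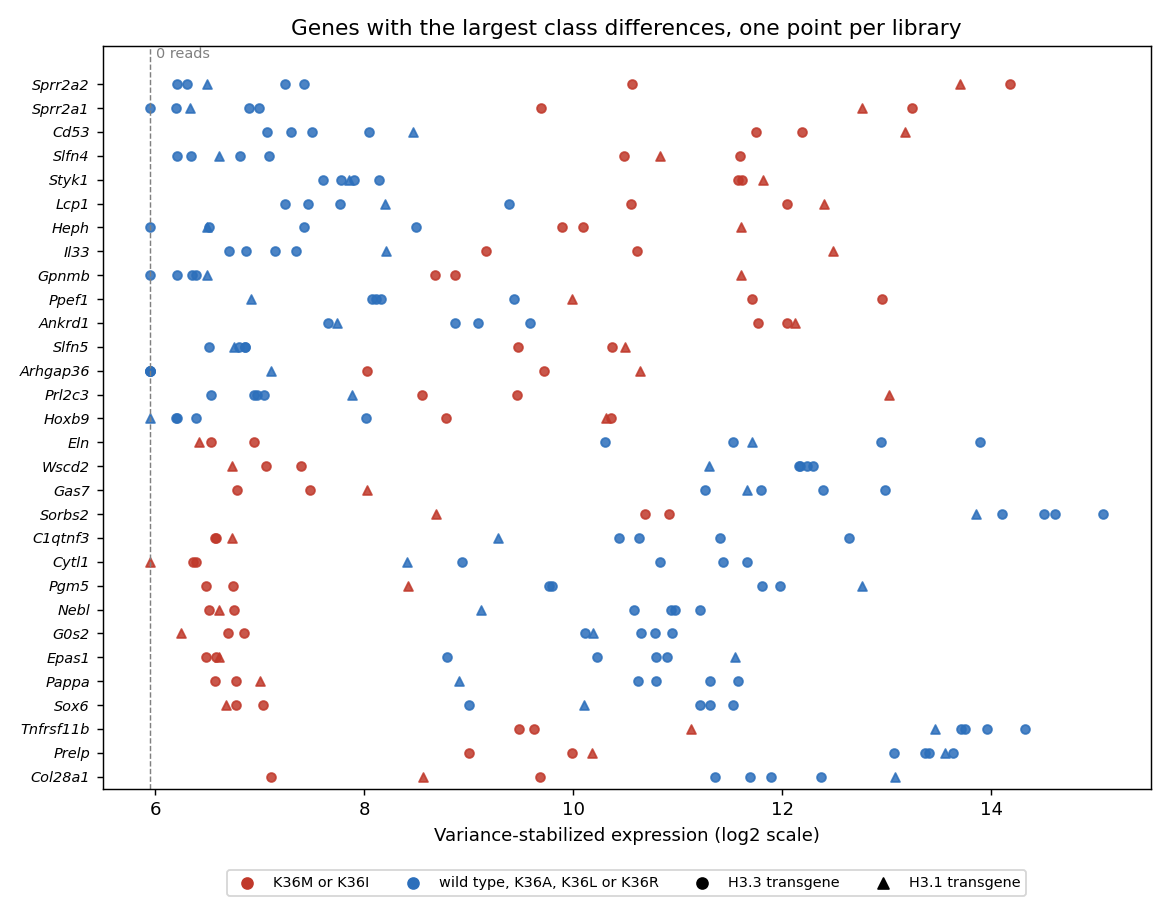
Variance-stabilised expression (log2 scale) of the 15 genes that rose most and the 15 that fell most, 1 point per library, with colour for class, shape for histone and a dashed line at the value of 0 reads. Cd53 lies at 39.2 to 243 normalised reads in the blue libraries and at 3327 to 9222 in the red ones, and no gene shown has overlapping classes.

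The count of called genes was lower without H3.3 K36M (1021), H3.3 WT (1211) or H3.3 K36I (1245) and without the pair of libraries with the most 45S ribosomal reads (1171), and higher with array weights (4074) or histone as a covariate (2959). With library medians set equal, 1961 genes were called, 1156 higher and 805 lower, a share of 58.9% higher against 48.6% as deposited. Without the filter 2530 were called, 1540 higher and 990 lower.

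Of 16 measured members of the chondrogenic list, 9 fell and 0 rose over all genes tested, and 13 fell when adjusted over the list alone, with a median of -1.94. Col2a1 (-2.24, SE 0.29) and Col11a1 (-3.43, SE 0.41), collagens of cartilage, fell, Col2a1 from 52980 to 10650 normalised reads. Sox9, the master transcription factor of chondrocytes, fell by 1.97 (SE 0.19), and Matn3 (-1.59, SE 0.10) and Fmod (-2.0, SE 0.19) fell as well. The camera test of limma gave adjusted p = 2.57e-07, and adjusted p = 0.348 with an estimated correlation. Leaving out each library in turn kept the camera call.

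Of 16 measured members of the joint Hedgehog and Notch list, 6 fell and 0 rose, and 9 fell when adjusted over the list alone (median -0.45, camera adjusted p = 1.35e-04). The list no longer passed with an estimated correlation (adjusted p = 0.109 with an estimated correlation). The Notch ligand Jag1 fell by 2.77 (SE 0.20), and Notch1 (-1.95, SE 0.17), the Notch target Hey1 (-1.99, SE 0.37) and Lfng, which modifies Notch (-1.31, SE 0.20), fell too. Of the Hedgehog members, Smo fell by 0.41 (SE 0.10), whereas Gli1 (-0.56, SE 0.39) and Ptch1 (-0.49, SE 0.27) did not pass.

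Collagen and matrix genes moved both ways. Of 44 measured members, 13 fell and 5 rose, and 17 fell and 7 rose when adjusted over the list alone (median -0.47, camera adjusted p = 0.0245, and adjusted p = 0.776 with an estimated correlation). Besides Eln, Fbn2 (-2.84, SE 0.59) and Col8a2 (-2.72, SE 0.27) fell. Col7a1, the collagen of anchoring fibrils, rose by 2.50 (SE 0.09), from 369 to 2625 normalised reads. Lamb1 rose by 2.03 (SE 0.37) and Col4a1 by 0.99 (SE 0.20), while Col1a1 (-0.22, SE 0.13) did not pass. Without H3.3 K36I, H3.3 K36M or H3.1 K36R the list no longer passed (camera adjusted p = 0.0738, 0.0753 and 0.0791). Relative to H3.3 WT its median lay at -0.54 in H3.3 K36I and -0.62 in H3.3 K36M. In H3.1 K36M it lay at only -0.04, with 10 members higher and 8 lower by at least 1. It was 0.29 in both K36R libraries, 0.01 in H3.3 K36A and -0.08 in H3.3 K36L.

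Camera called the inflammatory and interferon-stimulated lists upward, with few members past the test. In the cytokine and chemokine list, 4 of 17 measured members rose and 0 fell, with the same 4 rising when adjusted over the list alone (median 0.73, camera adjusted p = 0.0245, and adjusted p = 0.776 with an estimated correlation). Besides Il33 these were Lif (1.71, SE 0.17), Ptgs2, the inducible cyclooxygenase (1.44, SE 0.26), and Csf1, the macrophage growth factor (1.31, SE 0.25). Of 25 interferon-stimulated genes, 3 rose and 0 fell, likewise 3 when adjusted over the list alone (median 0.32, camera adjusted p = 0.0245, and adjusted p = 0.776 with an estimated correlation). They were Bst2 (1.57, SE 0.31), Psmb9 (1.5, SE 0.23) and Tap1 (1.32, SE 0.37), of which Psmb9 and Tap1 overlap on opposite strands. Without H3.1 K36M neither list passed (adjusted p = 0.302 for cytokines and 0.753 for interferon-stimulated genes), and without H3.3 K36A adjusted p was 0.0549 for both. Both lists were also high in H3.1 K36R, of the other class, with medians relative to H3.3 WT of 1.34 for cytokines and 0.90 for interferon-stimulated genes, against 0.82 and 0.03 in H3.3 K36I. The interferon-stimulated list also lost its call without H3.3 K36L (adjusted p = 0.0507) and with the filter set at a mean of 2 above the lowest value (adjusted p = 0.177).

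Hox genes split. Of 10 measured members, 4 fell and 1 rose, and 6 fell and 1 rose when adjusted over the list alone (median -0.29, camera adjusted p = 0.0429, and adjusted p = 0.348 with an estimated correlation). Hoxa2 (-0.92, SE 0.13), Hoxa3 (-0.78, SE 0.15), Hoxa4 (-0.65, SE 0.14) and Hoxa10 (-0.35, SE 0.09) fell, whereas Hoxb9 rose from 32.0 ± 66.1 (SD, n = 5) to 893 ± 491 normalised reads (SD, n = 3). The Hox call was lost without H3.3 WT (adjusted p = 0.0513), H3.3 K36A (0.0624), H3.3 K36I (0.0997), H3.3 K36M (0.0602) or H3.1 K36R (0.0631). Replication-dependent histone genes passed as a list towards lower values, although 0 of 33 members passed alone, over all genes or when adjusted over the list alone (median -0.18, camera adjusted p = 0.0259, and adjusted p = 0.776 with an estimated correlation). Hist1h1a (-0.89, SE 0.26) and Hist4h4 (-0.44, SE 0.26) had the largest differences of that list, and without H3.1 K36M its direction turned upward (adjusted p = 0.930). Its call was also lost without H3.3 K36A (adjusted p = 0.0549) or H3.1 K36R (0.103). Without the filter the Hox list turned upward too (adjusted p = 0.110).

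**Figure D3:**
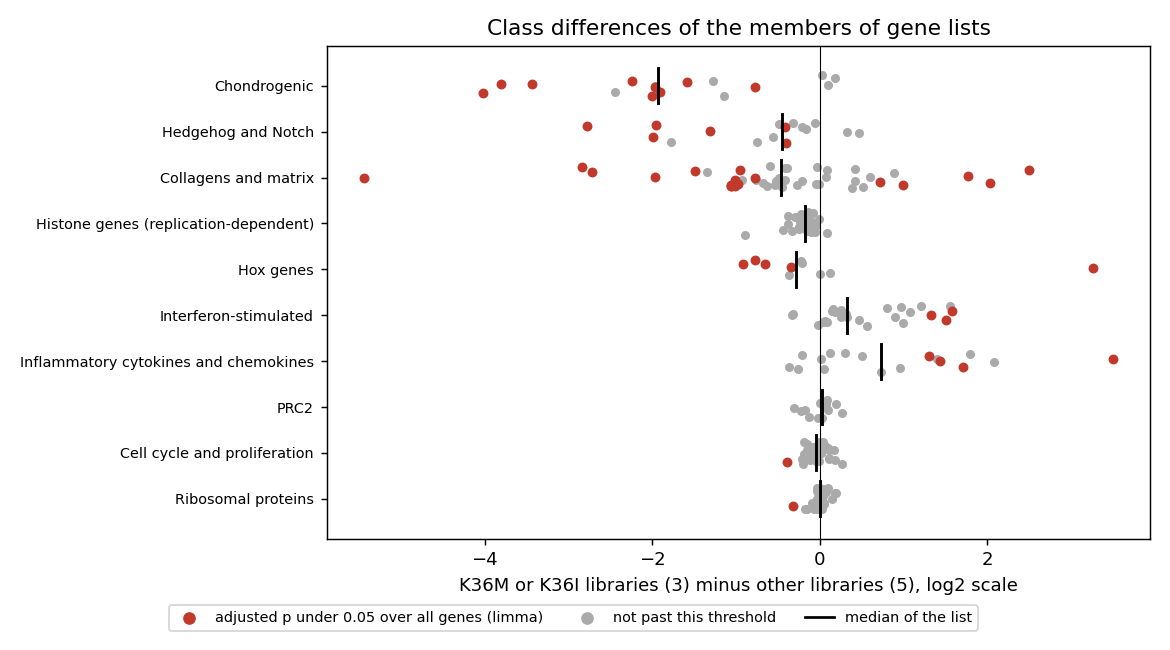
Class differences (log2 scale, 3 K36M or K36I libraries minus the other 5) of the measured members of 10 fixed gene lists, with 1 point per gene, red for adjusted p under 0.05 over all genes, and a bar at each list's median. The chondrogenic median lies at -1.94 and those of the PRC2, cell cycle and ribosomal protein lists at 0.02, -0.05 and -0.0018.

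Camera called 7 of 28 tested lists, and 19 of the 56 ways to choose 3 of the 8 libraries called at least as many, the real choice included. The list calls are therefore given with their member counts. In an exact two-sided permutation of the 8 libraries, the real choice gave the largest mean difference of the 56 for 6 lists, at exact p = 0.0179, the smallest that 56 choices allow (adjusted p = 0.0833 over 28 lists). These were the chondrogenic, Hedgehog and Notch, osteogenic, skeletal muscle, developmental transcription factor, and H3K36 demethylase and reader lists. The other lists that camera called had exact p = 0.0893 (collagen and matrix), 0.196 (cytokine), 0.196 (histone gene), 0.268 (interferon-stimulated) and 0.804 (Hox, with a mean of -0.01). The self-contained test fry for a shift in one direction also called 7 lists, of which the chondrogenic, Hedgehog and Notch, and Hox lists were shared with camera. It did not call the collagen and matrix (adjusted p = 0.344), cytokine (0.190), interferon-stimulated (0.380) or histone gene (0.380) lists.

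In the other lineage lists a minority of members passed over all genes tested. Among 16 osteogenic genes 3 fell and 2 rose (6 and 3 when adjusted over the list alone, camera adjusted p = 0.0794): Pth1r (-2.25, SE 0.49) and Alpl (-1.73, SE 0.41) fell, whereas Spp1, which encodes osteopontin, rose by 2.79 (SE 0.46), from 11470 to 84550 normalised reads. Among 19 adipogenic genes 3 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.877). The adipogenic regulators Cebpa (-2.41, SE 0.19) and Zfp423 (-1.67, SE 0.34) were among those that fell. Among 7 skeletal muscle genes, Tnni1 (-2.46, SE 0.19) and Mef2c (-2.22, SE 0.51) fell, by either adjustment (camera adjusted p = 0.203). Among 17 smooth muscle and myofibroblast genes 3 rose and 1 fell (4 and 2 when adjusted over the list alone, camera adjusted p = 0.127), with Actg2 up by 2.69 (SE 0.47) and Synpo2 by 1.32 (SE 0.19). Of 18 mesenchymal stem and stromal markers, Alcam (2.56, SE 0.35), Nes (1.24, SE 0.24) and Cd44 (0.50, SE 0.12) rose, by either adjustment (camera adjusted p = 0.322). Of 42 developmental transcription factors that are classical Polycomb targets, 10 fell and 2 rose (15 and 5 when adjusted over the list alone, camera adjusted p = 0.0715), with Sox8 (-1.92, SE 0.28), Lhx9 (-1.65, SE 0.35), Osr1 (-1.43, SE 0.35) and Lhx2 (-1.29, SE 0.14) falling most.

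Signalling lists were mixed. Rspo2, a potentiator of WNT signalling, fell by 3.02 (SE 0.26) while Wnt7a rose by 1.91 (SE 0.17) and Wnt9a by 1.31 (SE 0.21), among 14 WNT ligands and antagonists of which 3 rose and 1 fell (3 and 2 when adjusted over the list alone, camera adjusted p = 0.538). Of 14 WNT/beta-catenin response genes 4 fell and 1 rose (4 and 2 when adjusted over the list alone, camera adjusted p = 0.908), with Tcf7 at -1.93 (SE 0.48) and Bambi at -1.73 (SE 0.28). Of 24 BMP and TGF-beta genes 6 fell and 4 rose, also when adjusted over the list alone (camera adjusted p = 0.115). Camera called this list downward without H3.1 K36M (adjusted p = 0.0183), with library medians set equal (0.0416) and without the filter (0.0499). Relative to H3.3 WT its median lay at -0.53 in H3.3 K36I and -0.37 in H3.3 K36M, but at 0.20 in H3.1 K36M. It lay at 0.0035 to 0.20 in the other mutants. The BMP antagonist Grem1 rose by 2.69 (SE 0.43) and Ltbp1 by 1.84 (SE 0.33), and Tgfb2 (-1.83, SE 0.32) and Smad6 (-1.4, SE 0.20) fell. Of 17 matrix metalloproteinases and inhibitors 4 fell (4 fell and 1 rose when adjusted over the list alone, camera adjusted p = 0.344), led by Adamts12 (-2.34, SE 0.29) and Adamts1 (-1.83, SE 0.49). Of 20 p53 targets and CDK inhibitors 3 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.344), with Phlda3 at -1.29 (SE 0.20) and Polk at 0.75 (SE 0.15). Of 25 immediate early and stress genes 2 fell and 2 rose, also when adjusted over the list alone (camera adjusted p = 0.466), with Fos at -1.34 (SE 0.28) and Fosl1 at 1.21 (SE 0.18). Median and mean differ in sign for the WNT/beta-catenin response (0.22 and -0.11), p53 (0.19 and -0.01) and PRC2 lists (0.02 and -0.01).

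Few chromatin regulators, proliferation genes or ribosomal genes passed the test. Of the H3K36 methyltransferases, 1 of 10 rose, Whsc1 by 0.32 (SE 0.08, adjusted p = 0.0305), also when adjusted over the list alone (camera adjusted p = 0.741). Setd2 (-0.09, SE 0.08), Nsd1 (0.16, SE 0.12), Whsc1l1 (-0.11, SE 0.10) and Ash1l (-0.08, SE 0.08) did not pass. Among 19 H3K36 demethylases and readers Msh6 rose by 0.42 (SE 0.07) and Kdm4c fell by 0.30 (SE 0.07), by either adjustment (camera adjusted p = 0.348). Of 13 PRC2 genes 0 passed by either adjustment (camera adjusted p = 0.923), with Ezh2 at -0.31 (SE 0.11), Suz12 at 0.26 (SE 0.10) and Eed at 0.05 (SE 0.07). Of 20 PRC1 genes 2 rose by either adjustment (camera adjusted p = 0.761), Pcgf5 by 1.54 (SE 0.24) and Bcor by 0.35 (SE 0.07). Of 12 H3 genes and chaperones 0 passed by either adjustment (camera adjusted p = 0.928, direction upward against a mean of -0.02). The H3.3 genes H3f3a (-0.17, SE 0.14) and H3f3b (-0.52, SE 0.19) were among those that did not pass, and their reads were not told apart from those of the transgenes. Of 35 cell cycle genes only Ccna2 passed (-0.39, SE 0.08), by either adjustment (camera adjusted p = 0.400). Of 37 ribosomal protein genes only Rpl15 passed (-0.32, SE 0.08), and 0 when adjusted over the list alone (camera adjusted p = 0.987). Without H3.1 K36M, however, camera called this list upward (adjusted p = 5.95e-04). Relative to H3.3 WT its median lay at 0.13 in H3.3 K36I and 0.08 in H3.3 K36M. It lay at -0.39 in H3.1 K36M and -0.21 in H3.1 K36R, and at -0.09 to 0.03 in the other H3.3 mutants. Of 23 imprinted genes only Peg3 passed (2.14, SE 0.42), by either adjustment (camera adjusted p = 0.344).

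Few markers of other cell types passed over all genes tested. Of 9 measured neural and glial markers only Map2 passed (-2.14, SE 0.23), by either adjustment (camera adjusted p = 0.0796). In this list 8 members lay lower in the K36M and K36I lines (median -0.61). Camera called it with library medians set equal (adjusted p = 0.0383) and without H3.1 K36R (adjusted p = 0.0445). The remaining lists kept under 5 genes and had no list test. Of 4 measured leukocyte markers Cd53 rose over all genes, and 4 rose when adjusted over the list alone. Ptprc, which encodes the pan-leukocyte antigen CD45, stayed between 0 and 7.9 normalised reads in every library. Of 4 epithelial markers Krt7 rose by either adjustment (2.26, SE 0.17), from 6.77 to 304 normalised reads, whereas Epcam stayed between 0 and 2.2. Of 4 endothelial markers Erg (-2.47, SE 0.36) and Tek (-2.41, SE 0.23) fell by either adjustment. Of 3 germline genes Sycp3 fell by either adjustment (-0.49, SE 0.10).

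The comparison of K36M with K36R, the substitutions made in both histones, asked whether the same genes stand apart when the control is another mutant. With 2 libraries a side, Sprr2a2 rose by 7.59 (SE 0.23, adjusted p = 0.00748) and Sprr2a1 by 6.86 (SE 0.25), followed by Slfn4 (4.81, SE 0.32), Cd53 (4.43, SE 0.37), Lcp1 (4.39, SE 0.30) and Heph (4.35, SE 0.51). Eln fell by 6.12 (SE 0.73, adjusted p = 0.0410), followed by Wscd2 (-4.88, SE 0.35), Pgm5 (-4.70, SE 0.63), Col28a1 (-4.65, SE 0.62), Epas1 (-4.34, SE 0.45) and Gas7 (-4.05, SE 0.44). In all, 222 genes passed limma's test, 97 higher and 125 lower in K36M, of which 204 passed in the same direction in the class comparison, which contains these libraries. With histone as a block 639 genes were called, with voom 58, without the filter on low values 0 (limma, 3080 at unadjusted p under 0.05). Without either K36R library limma called 0 genes (1223 at unadjusted p under 0.05 without H3.3 K36R and 1259 without H3.1 K36R), and without H3.3 K36M or H3.1 K36M it called 347 and 471.

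The comparison of H3.1 with H3.3 within the K36M and K36R lines asked what differs between the histones carrying the same substitution. The complement gene C3 and the chemokine genes Cxcl5 and Cxcl1 were higher in the H3.1 lines. C3, the central complement component, was higher by 6.79 (SE 0.13, adjusted p = 0.00251), at 16312 and 25533 normalised reads in the H3.1 libraries and at 18.8 to 128 in the 6 H3.3 libraries. The neutrophil chemoattractant gene Cxcl5 was higher by 4.64 (SE 0.12, adjusted p = 0.00506) and Cxcl1 by 2.86 (SE 0.12). Serpina3g (5.18, SE 0.24), Serpina3f (4.06, SE 0.17) and Serpina3h (3.69, SE 0.22) are close copies of a serine protease inhibitor family on chromosome 12, so their reads may be shared. Tmem176b was higher by 5.01 (SE 0.30), Steap4 by 4.02 (SE 0.17), the inflammatory caspase gene Casp4 by 2.84 (SE 0.17) and Trim30a by 2.55 (SE 0.16), while Mal (-4.11, SE 0.19) and Medag (-2.77, SE 0.13) were lower. These 12 genes, 10 higher and 2 lower, passed limma's test with 1 residual degree of freedom, so the SEs rest mostly on the spread borrowed across genes. Without the filter limma called 0 (1957 at unadjusted p under 0.05), without the substitution term 0 (839 at unadjusted p under 0.05), and voom called 9. A test of whether the class difference itself differed between the histones called 0 genes (limma, 1582 at unadjusted p under 0.05).

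Each mutant was also set against H3.3 WT, with 1 library a side and therefore no test and no replicate check. H3.3 K36M differed by at least 1 in 1235 genes (608 higher, 627 lower) and H3.3 K36I in 1084 (491 and 593). H3.3 K36A differed in 295 (108 and 187), H3.3 K36R in 250 (151 and 99) and H3.3 K36L in 146 (74 and 72). H3.1 K36M differed in 1465 (864 and 601) and H3.1 K36R in 473 (296 and 177), both of which also differ from WT in histone. As log2(value + 1) of recovered reads the H3.3 counts were 1852 for K36M and 1762 for K36I. They were 768 for K36A, 717 for K36R and 516 for K36L, so the contrast between mutants was relatively smaller on that scale.

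In the H3.3 K36M library Sprr2a2 (7.87), Sprr2a1 (7.04), the mesothelial antigen gene Msln (5.34), Slfn4 (5.25) and Cd53 (5.12) were highest relative to WT, and Eln (-6.00), Gas7 (-5.61), Pgm5 (-5.24), Wscd2 (-5.10) and Tnfrsf11b (-4.83) lowest. In H3.3 K36I they were Msln (4.92), Ppef1 (4.80), Pcdh11x (4.74), Cd53 (4.67) and Efemp1 (4.36), and Eln (-6.42), Pgm5 (-5.49), Colec10 (-4.94), Gas7 (-4.91) and Wscd2 (-4.77). In H3.3 K36L Cd55 (2.52), Pcdh11x (2.3), Krt14 (2.25), Msln (2.22) and Sprr1a (2.09) were highest, and Rspo3 (-2.92), Arhgap20 (-2.64), Fat4 (-2.38), Cnr1 (-2.28) and Cdh11 (-2.24) lowest. In H3.3 K36A they were Col9a1 (3.43), Pcdh11x (3.20), H19 (2.84), Lect1 (2.59) and Tmem47 (2.57), and Nov (-3.78), Arhgap20 (-3.74), Plxdc2 (-3.33), Pcdh9 (-3.28) and Dcn (-3.23). In H3.3 K36R they were Tenm3 (3.74), Kcnf1 (2.99), the imprinted genes Mest (2.97) and Ndn (2.80), and Fzd3 (2.69), with Pde3b (-3.66), B4galnt2 (-2.71), Aim2 (-2.67), Ppp1r1b (-2.33) and Sox6 (-2.3) lowest.

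In H3.1 K36M Sprr2a2 (7.39), Prl2c2 (7.05), C3 (6.85), Cxcl5 (6.58) and Sprr2a1 (6.56) were highest, and Eln (-6.53), Sorbs2 (-6.38), Wscd2 (-5.43), Mal (-5.32) and Cytl1 (-4.88) lowest. In H3.1 K36R C3 (7.50), Cxcl5 (5.05), Tmem176b (5.03), Tmem176a (5.0) and Lcn2 (4.87) were highest, and Mal (-4.68), Pde3b (-4.64), Medag (-4.41), Krt14 (-3.67) and Slurp1 (-3.38) lowest. The median of the chondrogenic list lay at -1.59 in H3.3 K36I, -1.52 in H3.3 K36M and -1.37 in H3.1 K36M, below every one of 10000 random lists matched on size and expression. It lay at 0.45 in H3.3 K36A and 0.14 in H3.3 K36L, at percentiles 100 and 98.9 of such lists. In H3.3 K36R it lay at -0.44 (percentile 0) and in H3.1 K36R at -0.0018 (percentile 48.0). Random genes were drawn independently, whereas the members of this list moved together (estimated correlation 0.27), so extreme percentiles come easily. The immediate early and stress list, for example, lay at percentile 0 in H3.3 K36A, K36L and K36R.

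To ask how far the other substitutions share the K36M pattern, the 200 genes highest and 200 lowest in H3.1 K36M relative to H3.1 K36R were read in each H3.3 mutant relative to H3.3 WT, libraries that had no part in choosing the genes. The mean of the higher set minus that of the lower set was 4.38 in H3.3 K36M and 4.20 in H3.3 K36I, with 95% bootstrap intervals over genes of 4.14 to 4.61 and 3.97 to 4.43. It was 0.89 in H3.3 K36A (0.72 to 1.06), 0.84 in H3.3 K36L (0.72 to 0.96) and 0.21 in H3.3 K36R (0.08 to 0.36). Each exceeded all of 10000 random lists matched on expression, the highest of which reached 0.35 for H3.3 K36M and 0.13 for H3.3 K36R. The random lists were not matched on how much genes vary between libraries or on how far they move together. These readings share the H3.3 WT library, and with 1 library per mutant the intervals cover the choice of genes, not the spread between cultures. On the leading component H3.3 WT lay furthest from the K36M and K36I libraries (32.5, against 20.4 in K36A, 24.4 in K36L and 26.4 in K36R). An unusual WT library could thus raise every score, so the small scores of K36A, K36L and K36R do not establish a shared pattern. Pearson correlations across genes, which are not independent replicates, were 0.743 for K36M, 0.733 for K36I, 0.361 for K36L, 0.298 for K36A and 0.140 for K36R. The genes were chosen relative to H3.1 K36R, so a K36R effect shared by both histones would lower the H3.3 K36R score and correlation. The low values of K36R therefore do not rank it below K36A and K36L in likeness to K36M. The scores also depend on the scale, which the intervals do not cover. As log2(value + 1) of recovered reads they were 7.48 in K36M, 7.15 in K36I, 1.93 in K36A, 1.82 in K36L and 0.31 in K36R.

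The same reading in the other direction, with genes chosen in H3.3 K36M relative to H3.3 K36R and read in H3.1, gave 3.95. Of the 200 highest genes in each histone 115 were shared, and of the 200 lowest 114, where 2.81 would be shared by chance. The correlation across genes of the K36M minus K36R difference between the histones was 0.702, with no library in common.

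**Figure D4:**
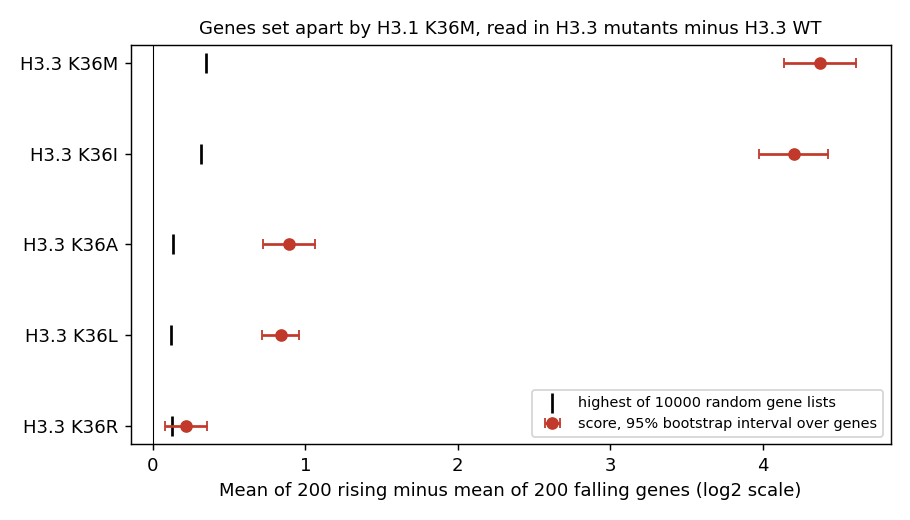
Mean of the 200 highest minus mean of the 200 lowest genes of the H3.1 K36M signature (log2 scale), read in each H3.3 mutant minus H3.3 WT, with 95% bootstrap intervals over genes and a black bar at the highest of 10000 random lists. K36M (4.38) and K36I (4.20) lie far right of K36A (0.89), K36L (0.84) and K36R (0.21).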

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

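The tests of chromosome copies for the leukocyte-associated genes and of chance placement of genes on chromosomes were chosen after the results they bear on were seen. The other tests of this part were set out before their results. A gap test on 35 sets of values singled out a library in 4 sets, and chance alone singles out about 1 set in 20.

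Within the 5 libraries without K36M or K36I, Arhgap36 stood out in H3.1 K36R at 7.10 on the log2 scale, with the other 4 libraries at 5.95, the value of 0 reads, so that any read in a single library would have given this outcome. Hoxb9 stood out in H3.3 K36A at 8.01, with the others between 5.95 and 6.39. Wscd2 was lowest in H3.1 K36R at 11.3, with the others between 12.2 and 12.3. Over all 8 libraries the share of reads from the 45S ribosomal precursor gene Rn45s was highest in H3.3 K36A at 5.24% (95% Wilson interval 5.23 to 5.24, which covers counting error only), with the others between 1.66% and 3.11%. The spread between cultures was not measured.

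Genes known from leukocytes (Cd53, Lcp1, Slfn4, Slfn5 and Gpnmb, picked after their values were seen) were higher in all 3 K36M and K36I libraries. Leukocytes in these cultures would bring their other abundant transcripts. The median of 10 such markers, Ptprc, Tyrobp, Fcer1g, Laptm5, Lyz2, Cd52, Csf1r, C1qa, C1qb and C1qc, was at most 0.0514% of the Cd53 level in the 3 libraries, which argues against that source, although Lyz2, present in all 8 libraries, reached 7.40% to 9.20% of it. Outside these 10, Cd14 lay at 445 to 695 normalised reads in the 3 libraries and at 139 to 387 in the others. Cd68 lay at 161 to 242 and 101 to 150. Emr1, Itgam, Lyz1, Cd3e, Cd79a and Aif1 stayed at or below 33.6 in every library. Extra copies of whole chromosomes are argued against as well, since all other tested genes on the chromosomes that carry these genes (3, 6, 11 and 14) had median class differences of at most 0.0218, whereas copies of short segments stay open. Expression by the mesenchymal cells themselves in association with the substitution remains a hypothesis, found and tested on the same data, and line-to-line selection is open.

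The 10 genes higher in H3.1 than in H3.3, among them C3, Cxcl5, Cxcl1 and Casp4, were higher in each H3.1 library than in each H3.3 library, except Trim30a, at 448 normalised reads in H3.1 K36R and 496 in H3.3 K36M. The H3.1 libraries are also the shallowest. After thinning of every library to 45448200 reads their median difference on the deposited scale was 4.02 against 4.04 before (99.5%). As log2(value + 8) of recovered reads it was 5.85 against 6.06 (96.4%). Values are divided by size factors, and these genes mostly have more reads in the shallower libraries. Thinning could therefore hardly have changed differences of this size, and its result adds no evidence on depth. The labels give 0 batches, so a culture, selection or library batch shared by the H3.1 lines cannot be told apart from the histone. The histone itself stays open as a biological explanation and was not tested separately from line history.

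Medians of whole chromosomes differed between libraries: chromosome 15 ranged from -0.13 in H3.1 K36R to 0.21 in H3.3 K36L and chromosome 18 from -0.18 in H3.3 K36L to 0.15 in H3.1 K36R (log2, relative to the mean of the libraries). The SD of these medians, 0.0598, exceeded that of 1000 random placements of genes, of which 0 were as large (highest 0.0141). A correction for GC content and transcript length left 97.1% of it, which argues against those properties as the source. After that correction the medians of both parts of a chromosome were correlated over all chromosomes and libraries together (r = 0.842). With parts shuffled among chromosomes, which could return some to their own chromosome, r was at most 0.556. Shifts that a library shows on most chromosomes enter both values of r. Copy number differences between the lines would give such a correlation, but copies were not measured. Not every chromosome moved as a whole: in H3.3 K36L the parts of chromosome 11 lay at 0.011 and 0.195, and those of chromosome 4 at 0.148 and -0.014. With chromosome medians subtracted, the class comparison called 2080 genes, 1168 higher and 912 lower, of which 1585 were among the 1887.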

How the results depend on the processing

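Alternatives with voom, chromosome medians subtracted, the fit without H3.3 K36A and H3.3 K36L and the exact list permutation were added after the data were seen, and the rest were planned. A change of sign was counted apart. It occurred for 2 class values of named genes, past the threshold in neither setting, and for 25 list values. Among these list values, 2 came from lists called as reported, the Hox list without the filter and the histone gene list without H3.1 K36M. The rest were past the threshold in neither setting. No gene called both as reported and under an alternative changed sign. The cause of the changes below was not tested unless a smaller number of libraries or another threshold explains them.

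The class comparison (1887 genes) called 4074 genes with array weights, 2959 with histone as a covariate, 1171 without H3.3 K36A and H3.3 K36L, 667 with a change of at least 1, and 3057 genes had classes that do not overlap. With 1 library left out it called 1021 (H3.3 K36M) to 2084 (H3.1 K36M), with 1211 without H3.3 WT and 1245 without H3.3 K36I, and 880 genes were called in every such fit. Other settings gave 1572 to 2545 genes. In the class comparison, calls of named genes were lost in 158, gained in 10 and kept their side in 2390 of the alternative values. Calls were lost in 55 and kept in 125 for K36M against K36R, and lost in 22 and kept in 56 for H3.1 against H3.3, with 0 reversed in any of these.

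K36M against K36R (222) called 0 genes without the filter and 58 with voom. With 1 library left out, when the lone library is taken to vary like the others, it called 0 to 471 genes: 0 without H3.3 K36R or H3.1 K36R, 347 without H3.3 K36M and 471 without H3.1 K36M. With histone as a replicate block it called 639 genes, which include the 222. The labels carry no replicate numbers beyond 1 per transgene, so no other pairing existed. H3.1 against H3.3 (12) called 0 genes without the filter and 0 without the substitution term. Array weights and leaving out a library were not run there, as no or too few residual degrees of freedom remained.

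Counts of genes differing from H3.3 WT followed the threshold. At a change of 0.5 they were 1119 for K36A, 2791 for K36I, 747 for K36L, 3008 for K36M, 1076 for K36R, 3910 for H3.1 K36M and 1929 for H3.1 K36R. At a change of 2 they were 50, 304, 20, 320, 22, 432 and 73 in the same order. On recovered reads as log2(value + 1) they were 768 for K36A, 1762 for K36I, 516 for K36L, 717 for K36R, 2202 for H3.1 K36M and 1064 for H3.1 K36R, and as log2(value + 8) 641 for K36A, 1660 for K36I, 412 for K36L, 588 for K36R and 923 for H3.1 K36R, scales that spread low values more. Of the values of named genes against WT, 63 moved by more than the SD over the other class and 0 changed sign.

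The H3.1 K36M signature kept its sign, and K36M and K36I stayed above K36A and K36L, under each setting run. With 50 genes each way it was 6.43 in K36M, 5.93 in K36I, 1.38 in K36A and 1.18 in K36L, with 100 genes 5.35, 5.06, 1.12 and 1.10, and with 500 genes 3.06, 2.91, 0.61 and 0.58. On log2(value + 1) it was 7.48, 7.15, 1.93 and 1.82 and on log2(value + 8) 6.44, 6.08, 1.51 and 1.41. That of K36R stayed within its interval, and correlations moved by less than 0.1, a bound chosen for this purpose.

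Camera (7 lists) called 11 lists with medians set equal, 0 with an estimated correlation and 3 without H3.3 K36A, where leaving out each library gave 3 to 7, and fry called 25 for change in either direction. The Hox list turned upward without the filter (adjusted p = 0.110) and the histone gene list without H3.1 K36M, where leaving out each library gave adjusted p = 1.86e-04 (without H3.3 K36I) to 0.930 (without H3.1 K36M). Depth limits genes of few reads: the filter left out 17061 genes.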

Other observations

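The test of gene span in this part was chosen after its pattern was seen, whereas the counts over other choices of libraries were set out before.

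Krt14, an epidermal keratin, lay at 18.5 normalised reads in H3.1 K36M, 31.9 in H3.1 K36R and 68.1 in H3.3 K36M, and at 616 in H3.3 K36I, 768 in H3.3 K36R, 1469 in H3.3 WT, 1899 in H3.3 K36A and 7440 in H3.3 K36L. Cdh1, the epithelial cadherin, lay between 293 and 1070 normalised reads in every library, highest in H3.3 K36I. Ocln, a tight junction gene, lay at 34.3 to 46.2 normalised reads in the 3 K36M and K36I libraries and at 0 in the other 5. These genes were picked after their values were seen. Krt14 and Cdh1 did not pass in the class comparison (adjusted p = 0.234 and 0.120), and Ocln lay under the filter on low values and was not tested.

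Against H3.3 WT, without a test, the median of the cytokine and chemokine list was 1.93 in H3.1 K36M and 1.34 in H3.1 K36R, against 0.82 in H3.3 K36I, 0.65 in H3.3 K36M and -0.07 to 0.33 in the other H3.3 mutants. That of the interferon-stimulated list was 1.16 and 0.90 in the H3.1 libraries and -0.28 to 0.27 in the H3.3 mutants. The median of the replication-dependent histone genes was -0.58 in H3.1 K36M and -0.17 to 0.04 in the other 6 mutants. The mesenchymal stem and stromal list stood at 0.56 in H3.1 K36M and 0.23 in H3.1 K36R, with -0.06 to 0.22 in the H3.3 mutants, and the smooth muscle list at 1.28 and 0.33, with -0.10 to 0.34. H3.1 K36M differs from H3.3 WT in both histone and substitution.

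The 1887 genes of the class comparison depended on the grouping. Of the 56 ways to choose 3 of the 8 libraries, 1, the real one, called as many, and the highest other choice called 10. A share of 1 in 56 is the smallest that these choices allow. Any other choice mixes the classes that part on the leading component, so low counts there could be foreseen. A batch or line history shared by the 3 lines would give the same outcome and was not tested. For gene lists chance could not be excluded, since 19 of the 56 choices called at least the 7 lists of the real one, the highest other calling 10.

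A hypothesis was that long genes fall more in the K36M and K36I lines, since called genes that fell had a median genomic span of 45.5 kb, against 27.4 kb for those that rose and 21.6 kb for those not called. Over all genes the rank correlation of span with the class difference was -0.07 (-0.04 with the class difference adjusted for transcript length and GC content), and 14 of the 56 choices of libraries gave one as negative, the lowest -0.18. Among the 3239 genes of longest span 427 were called lower and 242 higher, against 164 and 166 among the 3239 of shortest span, with 142 and 210 and then 183 and 243 in the groups between, so the counts did not follow span throughout. The 3 most negative other choices each held H3.3 K36I and H3.3 K36M, so the count of choices neither supports nor excludes the hypothesis, which stays open.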
